A study of Stylophora pistillata with 18 samples.

How the data were processed

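RNA from the reef coral Stylophora pistillata, which houses algal symbionts, was measured on 18 two-colour Agilent oligonucleotide arrays that carry 15744 spots each. Per the labels' protocols, total RNA was extracted with Trizol, 200 ng per sample were labelled with Cy3 or Cy5 together with spike-in control RNA, and both channels of an array held RNA of the study. The labels name 4 conditions, made from 2 light levels (200 and 500 µmol photons per square metre and second, over 15 days) and 2 feeding states (starved, or fed each day with brine shrimp larvae). They describe 1 aquarium for each condition. Replicates of a condition therefore shared their aquarium, p-values measure the spread between extracts within aquaria, and an effect of the aquarium itself cannot be separated from that of the treatment. The labels call the replicates biological and do not say whether each came from a colony of its own.

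Per the submitters' processing notes, the images were read with Agilent Feature Extraction 9.5.1.1, and Partek, version not given, was also used. The deposited scanner files hold intensity values, per the file headers: the mean brightness of each spot and the median brightness of its local background in both channels, before any subtraction. The processed signals in the same files are an intensity that the scanner software had background-subtracted, detrended and dye-normalized, per the file headers. The deposited log10 ratio of Cy5 over Cy3 comes from those processed signals, per the file headers. The deposited table of the series holds another unit, signed linear fold changes, 1 per array and feature, with 14617 features, of which 14559 were matched to a probe by name. Its values correlated with the arrays' own Cy5 over Cy3 log ratios at -0.986 to -0.584 (median -0.949 over the 18 arrays), so the authors' direction is Cy3 over Cy5. In the direction deposited, before it was turned, its column medians lay between -0.08 and 0.10 on the log2 scale. The steps behind its centring and scaling are not stated in the sources used here, and it was used only as an alternative.

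The background was corrected with normexp (offset 50), the log2 ratios were normalized within each array by loess with the 536 control spots at weight 0, and control spots and spots flagged as outliers by the scanner software (1304 spot measurements, 0.476%) were then left out. Saturated spots (0 to 5 per array) were kept. Spots of the same probe were averaged (45 probes were spotted more than once), which gave 14560 probes. A probe was tested when it was well above background in at least 4 of the 36 channel measurements, which kept 14394 probes and left out 166. Every ratio was turned to treated over control with the dyes named in the labels. Arrays of the same pair of RNA extracts were averaged, which made 15 pairs.

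A linear model (limma 3.58.1 in R 4.3.3, lmFit and eBayes) was fitted to the 15 pairs with 1 coefficient for each direct comparison and a dye term, leaving 11 residual degrees of freedom and 4.65 prior degrees of freedom. The direct comparisons were high over low light in starved corals (4 pairs), high over low light in fed corals (6 pairs) and fed over starved corals in low light (5 pairs). Whether the light response differed between fed and starved corals was tested as a contrast of the first 2, which share no extract. No array set fed against starved corals in high light, so that comparison was computed as a contrast of all 3. Feeding pairs share low light extracts with pairs of both light comparisons, and the fit treats all 15 pairs as independent. The SEs and p-values of the contrast of all 3 take no account of this sharing. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes tested. The dye term itself was called for 823 probes, with an SD of 0.125 over probes.

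Gene names are those the array files give. They resemble short names of protein database entries, some with an ending for another organism (_HUMAN, _CAEEL), and such an ending does not say which organism the RNA came from. A probe counted as named (8337 probes, 7212 distinct names) unless its name was that of a gene model, contig, read or uncharacterized protein. The pattern for these was finished after the probes with the largest changes had been seen. None of the 14560 distinct names matched an identifier in the reference table given for the coral (0 matched), so no positions are given. Among 798 names carried by several probes, 41 of the 183 with at least 2 called probes had calls in both directions in starved corals, 14 of 62 in fed corals and 2 of 33 in the contrast of the light responses. Each named value is that of 1 probe.

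Before the data were examined, the design, the other settings to try, the rule for named genes and 25 gene lists were fixed. The lists were written as protein descriptions, and since the files give short names only, they were translated into stems of those names after the names had been seen and before any comparison was computed. They held 1204 of the probes tested, 10 of them in 2 or more lists. The lists cover antioxidant enzymes, cytochromes P450, chaperones, proteasome and ubiquitin, calcification and ion transport, fluorescent proteins, ribosomal proteins, glycolysis and gluconeogenesis, respiration (citric acid cycle and oxidative phosphorylation), fatty acid oxidation, lipid and sterol synthesis, nutrient transport, nitrogen assimilation, innate immunity, apoptosis, DNA repair, cell cycle and replication, the circadian clock and extracellular matrix. Markers of cell types form the rest: digestive gland cells, stinging cells, neurons, muscle, germ line and the photosynthesis of the symbiont. The list of fluorescent proteins matched 1 probe and was not tested, since a list needed 5. A further set of 204 probes whose names carry the symbiont's genus was formed after the names had been seen, and was tested apart from the lists. Lists were tested with limma's camera (preset correlation 0.01) on the 13574 probes measured in every pair, with fry and with camera's estimated correlation as alternatives, and p-values were adjusted over the 24 lists of a comparison. Beside each count over all probes, the count adjusted over the list alone is given where it differs, and for lists not called the most it moved where that is small. Camera asks whether a list moved against all other probes, fry whether its members moved one way.

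The named genes are, in each direct comparison and in the contrast of the light responses, the 10 largest rises and the 10 largest falls among probes called and, in direct comparisons, changed the same way in every pair, with 1 probe per name, and up to 4 members of each list with the smallest p. If under 10 probes passed, the 10 with the smallest p were taken. Which of the list members so taken appear as examples was chosen after their values were seen. A gene that the rule takes is not reported here. Probes named for catalase, superoxide dismutase, carbonic anhydrase, heat shock proteins 70 and 90, cytochrome P450 and fluorescent proteins could be named everywhere. A fold written "at least" sets the brighter group's mean against the dimmer group's mean at no less than the lowest signal well above background, computed per channel after loess and Aquantile, and is open to dye bias.

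The spots well above background made up 42.9% to 99.8% (median 72.1%) of the probes per array in Cy3 and 73.0% to 99.7% (median 87.9%) in Cy5. The number of arrays limits the precision. The arrays lie on slides of 2 sets and were scanned in 2 batches: the first holds 8 arrays of the older slide set, the second 8 arrays of the newer set and 2 repeat arrays of starved pairs 2 and 3 on the older set. Each batch holds all 3 direct comparisons. Alternatives covered the background correction, the scanner software's processed signals, the deposited table, Aquantile, median centring in place of loess, both filters on dim probes, the dye term, slides, arrays left unaveraged, array weights, the variance model, each comparison fitted from its own arrays, separate channels (statmod 1.5.0) with and without a replicate block, thresholds, list tests, 1 probe per name and each pair left out in turn. The scan batches, the repeat arrays, the low light starved extracts 1 and 4 and the list tests with each pair left out were added after the data had been seen. Tables were read with jsonlite 2.0.0, and figures drawn with matplotlib 3.10.9.

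The steps after normalization and filtering, from averaging arrays to the calls, were tested on simulated log ratios with 200 of 14394 probes changed. The simulated noise was independent between probes and between pairs, so correlated probes and shared extracts were not tested. At changes of 1.25, 1.5 and 2-fold it recovered 11.9%, 76.1% and 100% of the changed probes in the starved light comparison, with 4 false calls among 129. It recovered 35.8%, 92.5% and 100% in the fed light comparison (7 false among 159), and 31.3%, 89.6% and 100% in the feeding comparison (9 false among 156). A shift of 0.2 in the chaperone list was found as 0.21, 0.20 and 0.19 in these comparisons, and 0 of 22 other lists were called in each. With independent probes, this cannot test the correlation preset for camera.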

Results

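Transcript levels were compared in the coral Stylophora pistillata under 4 conditions: low light starved, low light fed, high light starved and high light fed. High light, 500 µmol photons per square metre and second against 200 in low light, was applied for 15 days to make the colonies bleach, that is, lose their algal symbionts or the pigments of these. Both channels of each of the 18 arrays held coral RNA, so that a pair of conditions was compared directly. High over low light was measured in 4 pairs of starved and 6 pairs of fed corals, and fed over starved in 5 pairs in low light. Each condition was 1 aquarium, so that treatment and aquarium cannot be told apart. The p-values measure the spread between extracts within aquaria. Changes are given as log2 ratios with the standard error (SE) of the fit. Of 14394 probes tested, 5890 were well above background in every channel measurement.

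Arrays of the same extracts gave similar ratios across probes. The repeat arrays of starved light pairs 2 and 3 correlated with their first arrays at 0.891 and 0.832, and the dye swap of feeding pair 6 at 0.771. Both repeat arrays of starved pairs give the slide position of another array, of fed light pairs 2 and 3, with which they correlated at 0.517 and 0.562, and they were kept as labelled. Without them, 4598 probes were called for light in starved corals and 917 for the difference of the light responses, against 4719 and 1096. Pairs within a comparison correlated at 0.70 to 0.87 (median 0.741) for light in starved corals and at 0.26 to 0.76 (median 0.546) for light in fed corals. The 5 feeding pairs correlated at -0.41 to 0.68 (median -0.185). The spike-in controls, which should return known ratios, had a slope of measured on nominal log ratio of 0.790 (median of 8 arrays) in the first scan batch and of 0.124 (median of 10 arrays) in the second. Their Cy3 signal was a median 90.9 times the background in the first batch and 17.4 times in the second, and their Cy5 signal 218 and 256 times. The scanner software's correlation of measured with nominal spike-in ratios was a median 0.986 in the first batch and 0.212 in the second. The SD of the log2 ratios over probes was a median 0.377 and 0.354.

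The first question was how high light changed transcripts in starved corals. The largest rise was that of CP2U1, a cytochrome P450, at 6.13 (SE 0.131), or 70.2-fold (adjusted p = 4.3e-14, 4 of 4 pairs). UBE2C, a ubiquitin-conjugating enzyme of mitosis, rose 4.33-fold (2.12, SE 0.089). The largest fall was that of the chymotrypsin-like protease CTRL, which fell by 3.20 (SE 0.126), followed by the carbonic anhydrase CAH6 at -2.71 (SE 0.157) and the trypsin TRYP at -2.68 (SE 0.173). GALAXIN, named for a protein of the coral skeleton, fell by 2.45 (SE 0.127). In all, 2321 probes rose and 2398 fell in starved corals (4719 of 14394, n = 4 pairs), and 4513 of these moved the same way in all 4 pairs.

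Among the other large rises in starved corals were the yolk proteins VIT_ACITR (1.72, SE 0.319) and VITA2 (1.63, SE 0.229), the monooxygenase MOXD2 (1.65), MDGA1_MOUSE (2.05) and the peroxidase PXDN_CAEEL (2.13), of whose 6 probes 4 rose and 1 fell. Further large falls were LIT1 (-2.57), the protease TMPS6_HUMAN (-2.54), the sea anemone toxin TX60A (-2.53, SE 0.342), the lectins 209L2 (-2.49) and C209A (-2.42), and the protease inhibitor IVBI2_OXYSC (-2.44). All of these had adjusted p-values of 0.00058 or lower. TMPS6_HUMAN and MDGA1_MOUSE each have another probe called in the opposite direction.

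Chaperones, which help proteins to fold, rose as a group in starved corals, with 61 of 100 probes up and 8 down (64 and 9 adjusted over the list alone). Their median was 0.41 (adjusted p = 3.1e-13, camera). The heat shock proteins HS90B_DANRE (1.56, SE 0.108) and HSP7C_CAEBR (1.51, SE 0.113), the endoplasmin ENPL_CHICK (1.41, SE 0.066) and the mitochondrial chaperonin CH60 (1.35, SE 0.077) rose. HSP70_BRUMA rose by 1.22 (SE 0.076) and TRAP1 by 1.15 (SE 0.074), while a probe named HSP90 fell by 1.00 (SE 0.194). Proteasome and ubiquitin probes rose too (63 of 138 rose, 10 fell, adjusted p = 1.3e-06; 66 and 12 adjusted over the list alone). Among them were PSMD1_PONAB, a subunit of the proteasome (0.76, SE 0.074), and the deubiquitinase UBP14_MOUSE (0.76, SE 0.079). Probes of the cell cycle and replication rose (25 of 52 rose, 2 fell, adjusted p = 1.3e-06; 26 and 2 adjusted over the list alone). The replicative helicase subunit MCM5_XENTR stood at 1.03 (SE 0.070) and the cyclin-dependent kinase CDC2_ORYLU at 1.46 (SE 0.118). PCNA_MACFA rose by 1.07 (SE 0.081), although 2 of 4 probes named PCNA fell. These 3 lists kept their call with an estimated correlation (adjusted p = 0.00089, 0.017 and 0.017).

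Respiration also rose in starved corals, with 49 of 114 probes up and 13 down (61 and 13 adjusted over the list alone). Its adjusted p was 3.0e-05, and adjusted p = 0.072 with an estimated correlation. SUCB2, a subunit of succinyl-CoA ligase, rose by 0.87 (SE 0.086), whereas COX1_METSE, a subunit of cytochrome c oxidase, and DHSA_RICCN, a subunit of succinate dehydrogenase, fell by 2.13 (SE 0.195) and 1.60 (SE 0.110). Of the antioxidant probes, 23 of 64 rose and 5 fell (25 and 6 adjusted over the list alone; adjusted p = 0.00052, and adjusted p = 0.092 with an estimated correlation). They included TXNL1, a thioredoxin-like protein (1.24, SE 0.078), the peroxiredoxin PRDX6_CHICK (0.88, SE 0.074) and the superoxide dismutase SODC (0.73, SE 0.085). None of the 5 catalase probes of the array was called. Germ line markers rose (5 of 9, 0 fell; adjusted p = 0.0038, and adjusted p = 0.097 with an estimated correlation), and the yolk protein VIT2 was among these at 1.46 (SE 0.182). As a group, the cytochromes P450 were not called (10 of 37 rose, 8 fell; adjusted p = 0.41), although CP3AC rose by 0.95 (SE 0.092). CP1A2, not well above background in low light, rose at least 2.32-fold (adjusted p = 3.8e-07).

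Transcripts of the symbiont's photosynthesis fell in starved corals under high light, with 11 of 13 probes down, 0 up and a median of -1.50 (adjusted p = 5.2e-07, and adjusted p = 0.072 with an estimated correlation). The ferredoxin-NADP reductase FENR fell by 1.97 (SE 0.185), the photosystem I subunit PSAE1 by 1.74 (SE 0.141) and the cytochrome CYC6 by 1.73 (SE 0.156). In the set of 204 probes named for the symbiont's genus, 33 rose and 63 fell (38 and 65 adjusted over the set alone; p = 0.026 for the set, and p = 0.23 with an estimated correlation). Calcification and ion transport probes fell (20 of 46, 0 rose; adjusted p = 3.0e-05, and adjusted p = 0.072 with an estimated correlation). The carbonic anhydrase CAH2_MOUSE stood at -2.16 (SE 0.181) and the calcium channel subunit CA2D1 at -1.08 (SE 0.115). Digestive enzymes fell as well, with 12 of 30 probes down and 1 up (13 and 2 adjusted over the list alone; adjusted p = 0.00081, and 0.017 with an estimated correlation). The carboxypeptidase CBPA2_HUMAN (-1.39, SE 0.119) and the trypsin TRY3 (-1.32, SE 0.126) were among these.

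Lower in high light were also the markers of stinging cells (4 of 5 fell, median -1.29; adjusted p = 0.0014, and adjusted p = 0.086 with an estimated correlation). The pore-forming toxin ACTP3_RADMG was among them at -1.38 (SE 0.176). Neuronal markers fell (12 of 42, 2 rose; adjusted p = 0.035, and adjusted p = 0.072 with an estimated correlation). The synaptotagmin SYT4 stood at -1.02 (SE 0.070) and the glutamate receptor GRIK2 at -0.89 (SE 0.116). Extracellular matrix probes changed both ways (19 of 66 fell, 8 rose; 20 and 8 adjusted over the list alone). Their shift was downwards (adjusted p = 0.025, and adjusted p = 0.072 with an estimated correlation). The collagen COEA1_CHICK (-1.57, SE 0.087) and the proteoglycan PGCA_BOVIN (-2.18, SE 0.148) fell, and the fibrillin FBN1_MOUSE rose 2.84-fold. In the circadian list 6 of 12 probes fell and 1 rose (adjusted p = 0.025, and adjusted p = 0.072 with an estimated correlation). Among them were the transcription factor HLF (-1.35, SE 0.120) and the cryptochrome CRY1_SYLBO (-0.86, SE 0.110).

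The remaining lists were not called in starved corals. Their adjusted p-values and their rises and falls were 0.079 for ribosomal proteins (5 and 19 of 122), 0.15 for glycolysis and gluconeogenesis (13 and 8 of 37) and 0.051 for fatty acid oxidation (10 and 2 of 34). They were 0.54 for lipid and sterol synthesis (2 and 5 of 17), 0.73 for nutrient transport (20 and 21 of 114) and 0.13 for nitrogen assimilation (4 and 1 of 13). They were 0.079 for innate immunity (8 and 20 of 61), 0.37 for apoptosis (4 and 2 of 30), 0.085 for DNA repair (4 and 1 of 30) and 0.61 for muscle markers (4 and 8 of 27). Adjusted over the list alone, 3 ribosomal probes rose and 12 fell, 9 immunity probes rose and 22 fell, and the other counts moved by at most 1. The single fluorescent protein probe, GFPL_ANEMA, stood at 0.13 (SE 0.217, adjusted p = 0.73). Lipid and sterol synthesis and muscle had medians of 0.01 and 0.04 but means of -0.10 and -0.08.

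In starved corals, 3472 probes were called in the first scan batch alone and 3229 in the second (3 pairs each, pairs 2 and 3 being in both through their repeat arrays), and 6046 with the batch as a random block over all 18 arrays, which counts the 3 repeat arrays as further replicates. A dye term for each slide set gave 4594 calls, and the sets alone gave 3559 and 68 (3 pairs and 1 pair, the spread of the latter coming from the other comparisons). The medians of all 13 called lists kept their sign in each of these settings, which for the newer slide set rests on 1 pair. The chaperone median, for example, was 0.41 and 0.47 in the first and second scan batch, and the photosynthesis median -1.71 and -1.50. With arrays centred on their median in place of loess, 2580 probes were called, 60.4% of them higher against 49.2% in the fit reported. CA2D1, CRY1_SYLBO, GRIK2 and HSP90 among the genes named here then lost their call (adjusted p = 0.12, 0.18, 0.077 and 0.21), and so did the circadian and extracellular matrix lists (adjusted p = 0.13 and 0.17). On the probes well above background in all channel measurements, the circadian, extracellular matrix and neuronal lists lost their call (adjusted p = 0.086, 0.11 and 0.26), as did the circadian list with 1 probe per name (0.080). The symbiont-named set lost its call with median centring (0.26), on those probes (0.083), with 1 probe per name (0.30) and without starved pair 2 (0.054). The comparison's own arrays alone gave 2893 calls, and leaving out the pairs of low light starved extracts 1 and 4 gave 2884.

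In fed corals, high light raised PAO_MAIZE, a polyamine oxidase, 8.16-fold (3.03, SE 0.151, adjusted p = 7.2e-09, n = 6 pairs). SET1 (2.79, SE 0.178) and NRF6_CAEEL (2.72, SE 0.201) rose 6.93-fold and 6.58-fold. SAL_SILAS fell by 2.37 (SE 0.159), and the photosystem subunits PSBB and PSAB of the symbiont by 2.12 (SE 0.401) and 1.92 (SE 0.331). In all, 1168 probes rose and 1189 fell in fed corals (2357 of 14394), 1850 of them in the same direction in all 6 pairs. Changes of at least 1.5-fold numbered 98 rises and 483 falls.

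The glucose transporter GTR8_RAT (1.49, measured in 5 pairs) and UBE2C (1.32, SE 0.072) rose as well. MOXD2 (1.26), the steroid hydroxylase CP17A_ONCMY (1.23, 3 of 6 probes of that stem called, all up), the hexokinase HXK2 (1.06), the selenoprotein SELH (1.02) and the kinase CDC2_ORYLU (1.01) completed the 10 largest rises of the rule in fed corals. The 10 largest falls further held LIT1 (-1.87, SE 0.112, measured in 5 pairs), FENR (-1.69, SE 0.149), ETS2A, a transcription factor of the ETS family (-1.67), COX1_METSE (-1.67), the small GTPase ARF_CANAL (-1.63), the phosphoglycerate kinase PGK (-1.61) and the chaperone-like protease subunit CLPAB (-1.60). The adjusted p-values of these genes were 0.0014 or lower. EGR1, a transcription factor induced by many stimuli, stood at -1.36 in fed and -0.80 in starved corals.

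**Figure D1:**
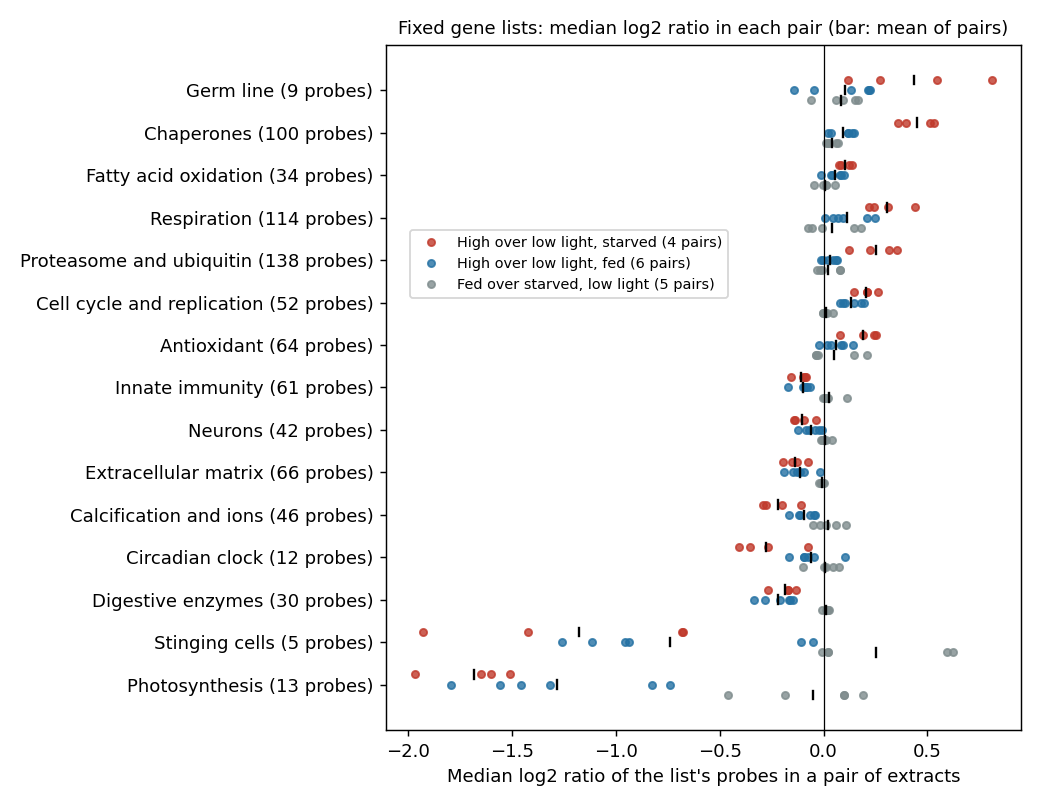
Median log2 ratio of the probes of 15 fixed gene lists in each pair of extracts, for high over low light in starved corals (4 pairs, red), high over low light in fed corals (6 pairs, blue) and fed over starved corals in low light (5 pairs, grey); black bars are the means of the pairs. The chaperone medians of the starved pairs, 0.36 to 0.53, lie above those of all 6 fed pairs, 0.02 to 0.14, whereas the photosynthesis medians of both overlap.

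Photosynthesis transcripts of the symbiont fell in fed corals too, with 11 of 13 probes down, 0 up and a median of -1.32 (adjusted p = 1.2e-10, and 0.035 with an estimated correlation). FCPA, a light-harvesting protein, fell by 1.45 (SE 0.140), CYC6 by 1.34 (SE 0.126) and PSAE1 by 1.32 (SE 0.114). Of the 204 probes named for the symbiont's genus, 59 fell and 16 rose (67 and 18 adjusted over the set alone; p = 1.6e-06 for the set, and 0.020 with an estimated correlation). Digestive enzymes fell, with 14 of 30 probes down and 2 up (16 and 3 adjusted over the list alone). Their adjusted p was 1.7e-05, and 0.010 with an estimated correlation. In this list CTRL fell by 1.35 (SE 0.101), TRYP by 1.22 (SE 0.140) and TRY3 by 0.78 (SE 0.102). Extracellular matrix probes fell (18 of 66, 2 rose; 24 and 2 adjusted over the list alone; adjusted p = 0.00039, and 0.019 with an estimated correlation). PGCA_BOVIN (-0.99, SE 0.119) and the astacin protease NAS7_CAEEL (-0.62, SE 0.102) were among them. Innate immunity probes fell (14 of 61, 3 rose; 15 and 4 adjusted over the list alone; adjusted p = 0.0038, and 0.035 with an estimated correlation). The mannose receptor MRC2_HUMAN stood at -1.26 (SE 0.126) and the transcription factor NFKB1_CHICK at -0.53 (SE 0.081).

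Among lists that shifted upwards in fed corals, the cell cycle and replication had 18 of 52 probes up and 2 down (21 and 2 adjusted over the list alone; adjusted p = 1.5e-05, and 0.019 with an estimated correlation). The ribonucleotide reductase RIR2_SCHPO (0.83, SE 0.080) and the cyclin CCNB (0.73, SE 0.079) rose, and PCNA_ORYSJ fell by 1.31 (SE 0.129). Chaperones had 21 of 100 probes up and 8 down (25 and 8 adjusted over the list alone), with a median of 0.09 (adjusted p = 0.0011, and 0.039 with an estimated correlation). ENPL_CANFA (0.66, SE 0.059), CH60 (0.64, SE 0.062), the co-chaperone DNJC8 (0.54, SE 0.066) and TRAP1 (0.46, SE 0.060) rose, and HSP90 fell by 1.20 (SE 0.156). Respiration had 28 of 114 probes up and 12 down (32 and 12 adjusted over the list alone; adjusted p = 0.00064, and adjusted p = 0.14 with an estimated correlation). SUCB2 stood at 0.67 (SE 0.069) and DHSA_RICCN at -1.37 (SE 0.095). Antioxidant probes were among these (12 of 64 up, 3 down; 15 and 4 adjusted over the list alone; adjusted p = 0.046). The proteasome and ubiquitin list shifted upwards by its test (12 of 138 up, 3 down; 8 and 1 adjusted over the list alone; median 0.03, 4 of 6 pairs; adjusted p = 0.048). Both lists lost their call with an estimated correlation (adjusted p = 0.31 and 0.21). TXNL1 rose by 0.56 (SE 0.063), GSHB_MOUSE, a glutathione synthetase, by 0.47 (SE 0.094), and the proteasome assembly factor PSMG4 by 0.33 (SE 0.055).

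Calcification and ion transport probes fell in fed corals, 9 of 46 with 1 up (10 and 1 adjusted over the list alone; adjusted p = 0.0046, and adjusted p = 0.17 with an estimated correlation). The carbonic anhydrases CAH14 and CAH6 stood at -1.37 (SE 0.131) and -0.93 (SE 0.126), the bicarbonate transporter S4A10 at -1.30 (SE 0.163) and GALAXIN at -0.76 (SE 0.103). Stinging cell markers fell (2 of 5, median -0.82; 3 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.14 with an estimated correlation). These were ACTP1 (-1.23, SE 0.174) and ACTP3_RADMG (-0.99, SE 0.142). Fatty acid oxidation shifted upwards by its test (4 of 34 rose, 1 fell; adjusted p = 0.040, and adjusted p = 0.068 with an estimated correlation), with ECHM_MOUSE, an enoyl-CoA hydratase, at 0.31 (SE 0.065).

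The other lists were not called in fed corals. Their adjusted p-values and their rises and falls were 0.19 for cytochromes P450 (8 and 2 of 37), 0.086 for ribosomal proteins (0 and 3 of 122), 0.40 for glycolysis and gluconeogenesis (9 and 6 of 37) and 0.57 for lipid and sterol synthesis (2 and 4 of 17). They were 0.11 for nutrient transport (18 and 7 of 114), 0.56 for nitrogen assimilation (0 and 3 of 13), 0.94 for apoptosis (2 and 3 of 30) and 0.11 for DNA repair (1 and 0 of 30). They were 0.44 for the circadian clock (2 and 4 of 12), 0.097 for neuronal markers (0 and 6 of 42), 0.36 for muscle markers (2 and 2 of 27) and 0.21 for germ line markers (1 and 0 of 9). Adjusted over the list alone, 0 ribosomal probes passed, 19 transport probes rose and 9 fell, and the other counts moved by at most 1. GFPL_ANEMA stood at 0.04 (SE 0.175). Glycolysis and gluconeogenesis had a median of 0.06 and a mean of -0.06, and its test pointed upwards.

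In fed corals, 831 probes were called in the first scan batch alone and 654 in the second (3 pairs each), 2586 with the batch as a random block, and 790 and 442 in the slide sets alone, against 2266 with a dye term for each set. The medians of the 12 called lists kept their sign in each of these settings except that of the antioxidant list, which was -0.0011 in the second scan batch. The chaperone median was 0.13 and 0.06 in the first and second batch, and the photosynthesis median -1.31 and -1.22. With median centring in place of loess, 765 probes were called, 52.7% of them higher against 49.6% in the fit reported (59.1% with the deposited table). With that centring, 14 genes named here lost their call (PCNA_ORYSJ, TRAP1, GSHB_MOUSE, CTRL, TRYP, TRY3, GALAXIN, CAH6, PGCA_BOVIN, NAS7_CAEEL, MRC2_HUMAN, NFKB1_CHICK, ECHM_MOUSE and HSP90, with adjusted p-values of 0.051 to 0.89). So did the proteasome, fatty acid oxidation and extracellular matrix lists (adjusted p = 0.054, 0.82 and 0.086). The changes of TRAP1, GSHB_MOUSE and ECHM_MOUSE were then larger than reported (0.63, 0.51 and 0.75). Those of the other genes were smaller, such as NFKB1_CHICK at -0.07, TRY3 at -0.27 and CAH6 at -0.43. TRAP1 also lost its call with the scanner software's processed signals (adjusted p = 0.36) and in the separate-channel fit (0.13), and NFKB1_CHICK with the deposited table (0.24). The antioxidant, proteasome and fatty acid oxidation lists lost their calls also with the processed signals (adjusted p = 0.066, 0.052 and 0.095) and without the dye term (0.10, 0.086 and 0.064), and the latter pair without background correction (0.067 each). The antioxidant, fatty acid oxidation and innate immunity lists lost theirs on probes well above background in all channel measurements (0.063, 0.052 and 0.069), and fatty acid oxidation with 1 probe per name (0.077). The proteasome list was no longer called when any single pair was left out except starved pairs 2 and 4 and fed pair 5 (adjusted p = 0.050 to 0.10). The antioxidant list was not without feeding pairs 1, 2, 4 or 5, starved pair 1 or fed pair 6 (0.050 to 0.061) or fed pair 3 (0.12), and fatty acid oxidation not without fed pairs 1, 3, 4 or 6 (0.095, 0.059, 0.053 and 0.051).

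**Figure D2:**
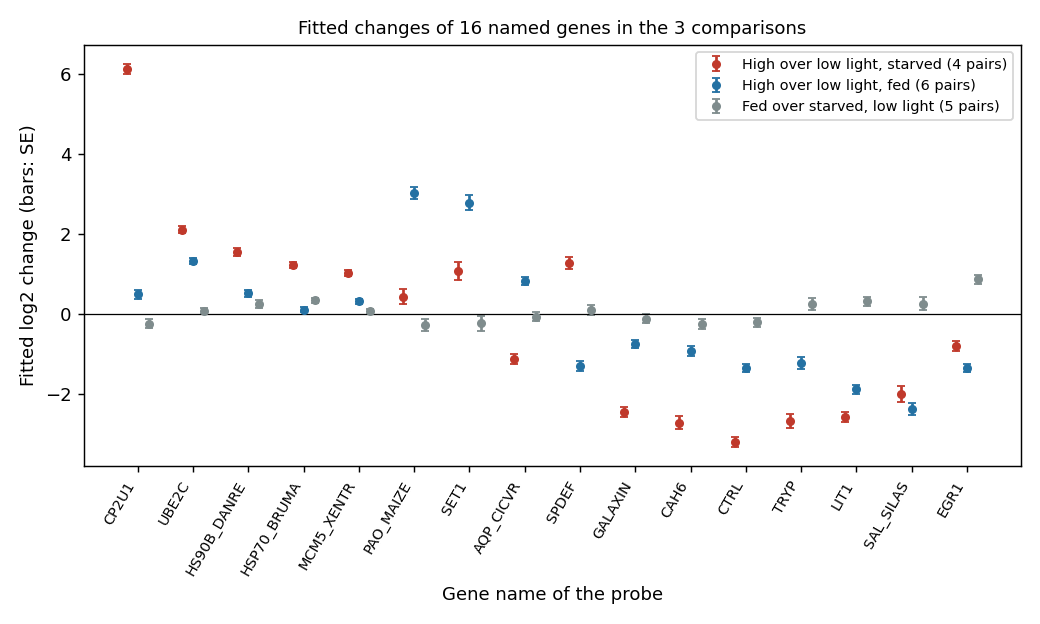
Fitted log2 changes (points) with their SE (bars) of 16 named genes in the 3 direct comparisons: high over low light in starved corals (4 pairs, red), high over low light in fed corals (6 pairs, blue) and fed over starved corals in low light (5 pairs, grey). CP2U1 stands at 6.13 in starved and 0.50 in fed corals, PAO_MAIZE at 0.44 and 3.03, and LIT1 at -2.57 and -1.87, while EGR1 alone was called for feeding.

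The next question was what feeding changed in low light. EGR1 was higher in fed than in starved corals, at 0.87 (SE 0.107) or 1.83-fold (adjusted p = 0.0071, 5 of 5 pairs), and no other probe was called by limma (1 of 14394, against 1066 at an unadjusted p under 0.05). The genes with the next smallest p were HSP70_BRUMA at 0.35 (SE 0.065, adjusted p = 0.28, 5 of 5 pairs), the co-chaperone DNJB4_PONAB at 0.60 (SE 0.128, adjusted p = 0.60, 4 of 5 pairs), ZC12C_MOUSE at 0.36 (SE 0.079, adjusted p = 0.60) and the phosphatase MTMR2_MOUSE at -0.35 (SE 0.079, adjusted p = 0.66). RT07 (-0.30), HMX3B (-0.31), ATG2B, an autophagy protein (-0.29), OPRK (0.27) and the actin ACT1_ACACA (0.44) had an adjusted p of 0.66 as well. HSP70_BRUMA and HSP7C_SAGOE (0.26, SE 0.072), of the chaperone list, passed when adjusted over the list alone (2 up, 0 down). The separate-channel fit called 7 probes, array weights 2, trended and robust variances 2, and this comparison's own arrays 0.

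As a group the 100 chaperones shifted upwards with feeding (median 0.05, 5 of 5 pairs; adjusted p = 0.0039, and adjusted p = 0.19 with an estimated correlation), with 0 probes called over all probes. Ribosomal proteins shifted downwards (0 of 122 called, median -0.04, 5 of 5 pairs; adjusted p = 0.039, and adjusted p = 0.40 with an estimated correlation), RS15_ELAOL being at -0.17 (SE 0.053, adjusted p = 0.66). The other 22 lists were not called, with 0 probes called in each. Their adjusted p-values were 0.12 for antioxidants, 0.89 for cytochromes P450, 0.23 for proteasome and ubiquitin, 0.48 for calcification and ion transport and 0.64 for glycolysis and gluconeogenesis. They were 0.115 for respiration, 0.76 for fatty acid oxidation, 0.46 for lipid and sterol synthesis and for nutrient transport. They were 0.10 for nitrogen assimilation, 0.115 for innate immunity and 0.13 for apoptosis. They were 0.28 for DNA repair, muscle and germ line, 0.33 for the cell cycle, 0.72 for the circadian clock, 0.89 for extracellular matrix, 0.84 for digestive enzymes, 0.115 for stinging cells, 0.91 for neurons and 0.97 for photosynthesis. The photosynthesis and extracellular matrix tests pointed downwards at medians of 0.02 and 0.01, and the circadian list had a median of 0.01 and a mean of -0.02. The symbiont-named set shifted upwards (median 0.06; p = 0.0014 for the set, and p = 0.097 with an estimated correlation), and GFPL_ANEMA stood at -0.14 (SE 0.187).

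EGR1 lost its call without feeding pair 1, 4 or 5 (adjusted p = 0.10, 0.096 and 0.088), without background correction (0.15), with the processed signals (0.056), with median centring (1.0), with the deposited table (0.57) and without the dye term (0.83). Its change lay between 0.78 and 1.03 in these settings, against 0.87. Without feeding pairs 1, 4 or 5, 0 probes were called, without feeding pair 2, starved light pair 3 or fed light pair 4, 2, and without starved light pair 2, 3. No probe was called for feeding within either scan batch or slide set, 1 with a dye term for each slide set, 3 with the slide and 6 with the scan batch as a random block. The chaperone median was 0.02 and 0.05 in the first and second batch, which hold 2 and 3 feeding pairs, and that of ribosomal proteins -0.02 and -0.05. The chaperone list lost its call with median centring (adjusted p = 0.24) and the ribosomal list with the processed signals (0.16), and by fry both did (0.11 and 0.30). The ribosomal list was not called without feeding pairs 2, 5 or 6 (0.056, 0.12 and 0.44) or fed light pairs 2, 4 or 5 (0.056, 0.056 and 0.058), and the chaperone list not without feeding pair 6 (0.055). Without feeding pair 5, 4 lists were called. The symbiont-named set lost its call with median centring (0.073) and by fry (0.094).

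Whether the light response differed between fed and starved corals was tested directly. CP2U1 stood at 0.50 in fed against 6.13 in starved corals, a difference of -5.64 (SE 0.173, or 49.7-fold, adjusted p = 1.2e-11). The ETS-family transcription factor SPDEF stood at -1.30 in fed and 1.29 in starved corals (difference -2.58, SE 0.197). The light response of the astacin protease NAS30 was 10.3-fold higher in fed corals (difference 3.37, SE 0.411), at 0.97 in fed and -2.40 in starved corals. That of PAO_MAIZE was 6.03-fold higher (difference 2.59, SE 0.248), at 3.03 in fed and 0.44 in starved corals. The lectins 209L2 and C209A, at -2.49 and -2.42 in starved corals, stood at 0.10 and 0.04 in fed corals (differences 2.59, SE 0.283, and 2.46, SE 0.276). In all, 1096 probes differed, 558 with a positive and 538 with a negative difference, and 495 of the 558 had fallen and 485 of the 538 had risen in starved corals, which is favoured because the starved estimate enters both values.

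Further positive differences were those of the aquaporin AQP_CICVR (1.96, SE 0.166), PPBI1 (1.95), TMPS6_HUMAN (1.91), IVBI2_OXYSC (1.88), CTRL (1.85, SE 0.166) and PP11_HUMAN (1.81, SE 0.420). AQP_CICVR stood at 0.83 in fed and -1.12 in starved corals. Further negative differences were those of PXDN_CAEEL (-2.44, 5 of 6 probes of that stem lower), MFGM_HUMAN (-1.59), TYRO_STRGA, a tyrosinase (-1.49), MLT7_CAEEL (-1.48), the ETS-family factor ELK4 (-1.43), the metalloproteinase inhibitor TIMP (-1.36), MDGA1_MOUSE (-1.31) and the chymotrypsin CTRB2_HUMAN (-1.22). Their adjusted p-values were 0.017 or lower.

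**Figure D3:**
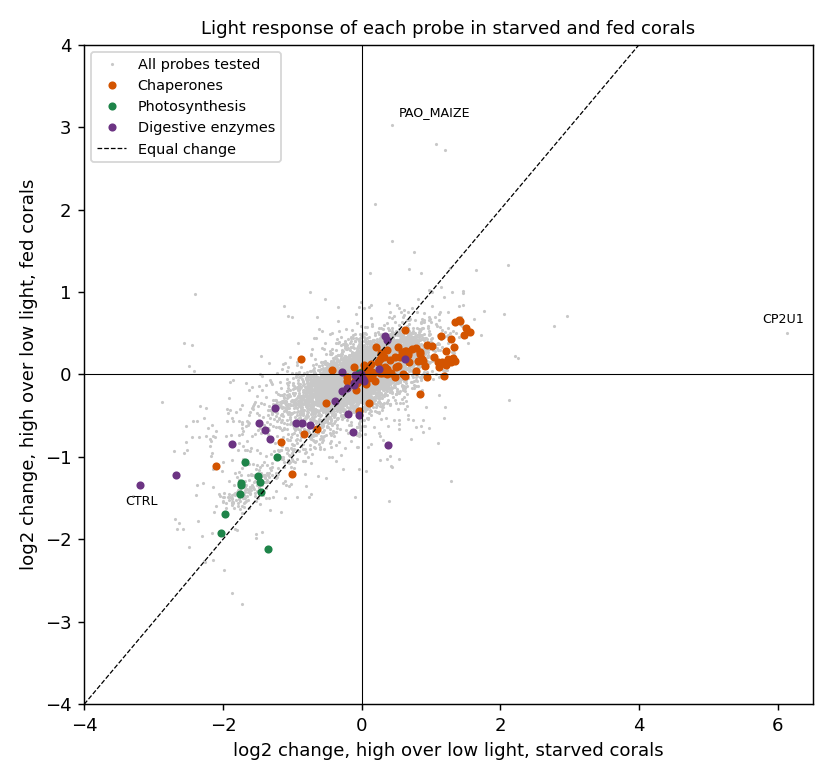
Fitted log2 change under high light of each probe tested in starved corals (horizontal axis) and in fed corals (vertical axis), with chaperones, photosynthesis and digestive enzymes coloured and the dashed line at equal change. Across probes the correlation is 0.716 and the slope 0.463, and CP2U1 (6.13 and 0.50), PAO_MAIZE (0.44 and 3.03) and CTRL (-3.20 and -1.35) lie far from the line.

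Chaperones formed the list with the smallest p: the difference was negative for 35 of 100 probes and positive for 1 (47 and 3 adjusted over the list alone). Their median difference was -0.32 (adjusted p = 5.2e-17, and 0.00028 with an estimated correlation). HSP83_DROAV differed by -1.12 (SE 0.116), HSP70_BRUMA by -1.11 (SE 0.10), HSP7C_SAGOE by -1.03 (SE 0.110) and the chaperonin subunit TCPZ by -0.95 (SE 0.097). The proteasome and ubiquitin list also differed downwards (26 of 138 lower, 1 higher; 42 and 3 adjusted over the list alone; median -0.19, adjusted p = 5.5e-07, and 0.020 with an estimated correlation). UBE2C stood at -0.79 (SE 0.118) and PSMD1_PONAB at -0.60 (SE 0.098). These were the only lists of the 24 that kept their call with an estimated correlation.

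Lower differences were further found for the cell cycle and replication (9 of 52 lower, 0 higher; 11 adjusted over the list alone; adjusted p = 0.00038, and adjusted p = 0.061 with an estimated correlation). MCM5_XENTR stood at -0.71 (SE 0.093). They were found for antioxidants (8 of 64 lower, 0 higher; 8 and 1 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.16 with an estimated correlation). PRDX6_CHICK (-0.68, SE 0.098) and SODC (-0.53, SE 0.113) were among them. Nitrogen assimilation shifted downwards by its test (3 of 13 lower, adjusted p = 0.0056), with the asparagine synthetase ASNS_CRIGR at -0.76 (SE 0.087). Germ line markers (1 of 9 lower, 3 adjusted over the list alone; adjusted p = 0.0049) and respiration (2 of 114 lower, 2 higher; 1 and 2 adjusted over the list alone; median -0.12, adjusted p = 0.014) shifted downwards by their tests as well. These lists lost their call with an estimated correlation (adjusted p = 0.14, 0.14 and 0.29). CYC_PECGU, a cytochrome c of the respiration list, had a positive difference of 0.86 (SE 0.156).

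Higher differences were found for calcification and ion transport (7 of 46 higher, 0 lower; 8 adjusted over the list alone; adjusted p = 0.00038, and adjusted p = 0.14 with an estimated correlation). CAH6 stood at 1.78 (SE 0.207), GALAXIN at 1.69 (SE 0.168) and CAH2_MOUSE at 1.21 (SE 0.24). Ribosomal proteins, with medians of -0.04 in starved and 0.04 in fed corals, shifted upwards by their test (3 of 122 higher, 1 lower; 0 adjusted over the list alone; adjusted p = 0.00038), with RS5_RAT at 0.34 (SE 0.085) and RL18A_HUMAN at 0.43 (SE 0.121). So did the circadian list (2 of 12 higher, 0 lower; adjusted p = 0.012). Both had an adjusted p = 0.095 with an estimated correlation. The photosynthesis list was not called (0 of 13 differed, median 0.22, adjusted p = 0.13), nor were digestive enzymes (6 of 30 higher, 3 lower; 0.074), stinging cells (2 of 5 higher; 0.065) or neurons (2 of 42 higher; 0.13). Muscle was not called (4 of 27 higher, 1 lower; 0.93), nor was extracellular matrix (8 of 66 higher, 4 lower; 0.93). Cytochromes P450 as a list were not called either (2 of 37 higher, 3 lower; 0.93). The medians of muscle, extracellular matrix and lipid and sterol synthesis were -0.10, -0.03 and -0.03 but their means 0.03, 0.07 and 0.02, and cytochromes P450 had a median of 0.03 and a mean of -0.12. Of the others, glycolysis (0.17), fatty acid oxidation (0.43), lipid and sterol synthesis (0.78), nutrient transport (0.14), innate immunity (0.91), apoptosis (0.17) and DNA repair (0.43) were not called. Adjusted over the list alone, 14 transport probes were higher and 8 lower (9 and 6 over all probes), 3 immunity probes higher and 5 lower (2 and 2), and the counts of the other lists not called moved by at most 1. The symbiont-named set had 19 of 204 probes lower and 6 higher (22 and 9 adjusted over the set alone) and was not called (adjusted p = 0.26, this set alone), and GFPL_ANEMA differed by -0.08 (SE 0.287).

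The number of probes whose light response differed depended on the processing and the pairs. It was 47 with median centring (40.4% positive, against 50.9% in the fit reported), and 699 with the deposited table (65.1% positive). It was 2084 with array weights, 1660 in the separate-channel fit, 615 without starved pair 3 and 634 without fed pair 5. It was 239 in the first scan batch alone, 469 in the second, 1375 with the batch as a random block, 200 and 1 in the slide sets, and 1028 with a dye term for each set. The medians of all 10 called lists kept their sign in these batch and slide settings, with the chaperones at -0.26 and -0.36 and the proteasome list at -0.11 and -0.21 in the first and second batch. With median centring, 25 of the named differences lost their call, among them those of CTRL (1.85, adjusted p = 0.074), CAH6 (1.79, 0.076), HSP70_BRUMA (-1.10, 0.34) and UBE2C (-0.87, 0.24), whose sizes were close to those reported, while those of CP2U1, SPDEF, NAS30, PAO_MAIZE, 209L2, C209A and GALAXIN stayed called. PRDX6_CHICK, SODC, RS5_RAT, RL18A_HUMAN and CYC_PECGU lost theirs with the deposited table (adjusted p = 0.085, 0.20, 0.23, 0.26 and 0.051), and RS5_RAT and RL18A_HUMAN with the processed signals (0.098 and 0.22). Without fed pair 1 the call ended for MFGM_HUMAN (adjusted p = 0.064), TYRO_STRGA (0.062), CTRB2_HUMAN (0.063), RS5_RAT (0.071) and RL18A_HUMAN (0.058). Without fed pair 5 it ended for the same genes (0.078, 0.058, 0.075, 0.062 and 0.13). Without starved pair 3 it ended for PP11_HUMAN (0.079), ELK4 (0.055), RS5_RAT (0.095) and RL18A_HUMAN (0.19), without starved pair 1 for TYRO_STRGA (0.052) and RL18A_HUMAN (0.053), and without starved pair 4 for TYRO_STRGA (0.053) and RS5_RAT (0.067). RL18A_HUMAN lost its call also without starved pair 2 (0.099) and fed pairs 3, 4 and 6 (0.062, 0.053 and 0.055). The respiration list was not called without fed pair 5 (0.13) or by fry (0.061). The respiration, circadian and germ line lists were not called on probes well above background in all channel measurements (0.058 each), nor was nitrogen assimilation with 1 probe per name (0.075).

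Between the light responses themselves, the correlation across probes was 0.716 (Spearman 0.635), with a covariance of 0.0902 against -0.00089 in simulations without effects, and all 24 combinations of a starved and a fed pair correlated above 0. The arrays of both share no extract, and probes are not independent replicates. In both starved and fed corals 828 probes rose and 903 fell, against 188 and 198 for independent lists, and 25 and 31 moved in opposite directions. Of the 4719 probes called in starved corals, 93.7% had the larger change there, which the choice of those probes favours. Their median size was 0.49 in starved and 0.20 in fed corals. Of the 2357 probes called in fed corals, 63.5% had the larger change in starved corals, with median sizes of 0.51 in starved and 0.38 in fed corals. Feeding shares extracts with both: its response correlated at 0.205 with that to light in starved corals (covariance 0.0114). Simulations without effects gave 0.342 and 0.0041, and the 2 feeding pairs that share no extract with the 4 light pairs gave -0.104. With light in fed corals the feeding response correlated at -0.082 (covariance -0.0029). Simulations gave -0.457 and -0.0044, and 3 feeding and 3 light pairs without shared extracts gave 0.295. Part of either value may come from the shared extracts. Because some feeding pairs ran against others across probes, the values from fewer pairs cannot show what the shared extracts add.

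Fed over starved corals in high light could be computed only indirectly, over all 3 direct comparisons, and its p-values take no account of shared extracts. In all, 435 probes differed, 246 higher and 189 lower. CP2U1, chosen after its values were seen, stood at -5.88 (SE 0.207, adjusted p = 9.8e-11). Chaperones were lower in fed corals (21 of 100 lower, 0 higher; 28 and 1 adjusted over the list alone; median -0.27, adjusted p = 1.1e-14, and 0.00056 with an estimated correlation), and so was the proteasome and ubiquitin list (7 of 138 lower, 1 higher; 15 and 1 adjusted over the list alone; adjusted p = 6.2e-06, and 0.036 with an estimated correlation). Cell cycle (5 of 52 lower, 7 adjusted over the list alone), antioxidant (2 of 64 lower) and germ line (0 of 9) lists shifted downwards with adjusted p-values of 0.0011, 0.021 and 0.021, and lost their calls with an estimated correlation (adjusted p = 0.090, 0.24 and 0.23). Calcification (3 of 46 higher, 5 adjusted over the list alone), stinging cells (1 of 5 higher, 3 adjusted over the list alone), ribosomal proteins (0 of 122), circadian (0 of 12) and digestive enzymes (4 of 30 higher; 6 higher and 1 lower adjusted over the list alone) shifted upwards with adjusted p-values of 1.7e-05, 0.0088, 0.021, 0.021 and 0.046. These lost their calls with an estimated correlation as well (adjusted p = 0.090, 0.19, 0.21, 0.12 and 0.13).

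The indirect count depended on the processing and the pairs, and it was higher with array weights and in separate channels, as given below. It was 8 with median centring (25.0% higher, against 56.6% in the fit reported), 202 with the deposited table (75.7% higher), 230 with the processed signals, 7 and 44 in the first and second scan batch, 634 with the batch as a random block, 5 and 1 in the slide sets, and 196 without low light starved extracts 1 and 4. Leaving out starved pair 3, fed pair 5, feeding pair 4 or starved pair 4 gave 239, 275, 288 and 289. The antioxidant list was not called without starved pair 1, feeding pair 6 or fed pair 5 (0.054, 0.069 and 0.055), nor germ line without starved pair 1 or fed pair 5 (0.062 and 0.057). Ribosomal proteins were not called without starved pair 1 or feeding pair 4 (0.076 and 0.098), nor with median centring (0.70), and the circadian list was not with median centring (0.090). Digestive enzymes were not called without starved pairs 3 or 4 (0.17 and 0.063), feeding pairs 4 or 6 (0.068 and 0.069) or fed pairs 4 or 6 (0.064 and 0.091). On probes well above background in all channel measurements, the ribosomal, circadian and germ line lists were not called (0.054, 0.063 and 0.12), with 1 probe per name the ribosomal, digestive and germ line lists were not (0.051 each), and by fry the antioxidant and germ line lists were not (0.077 and 0.069).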

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

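The tests of the feeding pairs, of a weaker response, of symbiont RNA and of feeding in high light with the feeding pairs turned were chosen only after the results were seen, as were the settings by scan batch and without low light starved extracts 1 and 4. Chance was tested by other arrangements of the pairs. Turning the pairs of light in fed corals in the other 31 ways called at most 253 probes, against 2357, so that 1 of 32 arrangements called as many. This is the lowest share that 32 arrangements allow, and it argues against chance without excluding it. Of 100 drawn reassignments of the light pairs to fed and starved corals, 1, the real one, called as many probes as the 1096 whose light response differed (highest other 328). This argues against chance without excluding it. For the 435 probes of feeding in high light, reassigning the light pairs alone called at most 410, but the feeding pairs enter this contrast too. With these turned as well, 3 of 100 drawn arrangements called as many, the real one included, a share under 0.05, yet 1 that mixed starved and fed pairs called 1647. That is several times the real count and points to a structure of the pairs, which was not tested. For this count the arrangements are not taken to argue against chance. For light in starved corals (1 of 8 arrangements; 4719 probes, highest other 1) and for feeding in low light (1 of 16; 1 probe, highest other 0) the arrangements are too few for a share under 0.05.

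The light response differed between fed and starved corals, by the test of the difference itself, for 1096 probes and for 10 gene lists. The median differences were -0.322 for chaperones, -0.188 for proteasome and ubiquitin, -0.0906 for the cell cycle, -0.0991 for antioxidants, -0.121 for respiration, -0.282 for nitrogen assimilation and -0.269 for germ line markers. They were 0.113 for calcification and ion transport, 0.0881 for ribosomal proteins and 0.190 for the circadian clock. With an estimated correlation 2 of the 10 lists, chaperones and proteasome and ubiquitin, kept their call, and the other 8 did not (adjusted p = 0.061 to 0.29).

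Chaperone transcripts rose less under high light in fed than in starved corals, with a median difference of -0.322. Ratios compressed in the second scan batch, where the spike-in slope was low, are argued against by the first batch alone, in which the difference was -0.258 (SE 0.0876, within 1 SE of the bound of -0.2) and the starved pairs lay at 0.258 to 0.528 against 0.118 to 0.145 in the fed pairs, while the second batch gave -0.358; a shared state of low light starved extracts 1 and 4 is argued against by a difference of -0.300 (SE 0.0894) with starved pairs 2 and 3 alone. The photosynthesis list was not weakened as much as the chaperones: its fed median was 0.883 of the starved one (lowest fed pair 0.495), against 0.225 for chaperones. This cannot decide on a weaker response of all transcripts, the symbiont's included. The first bound set, a photosynthesis median at least as low in fed corals, was not met (-1.32 against -1.50). The bound used was set after these values were seen, and loss of symbionts could lower this list as well. A weaker response of the coral's own genes stays open: among probes that rose in starved corals, the ratio of the fed to the starved median was 0.257 for the 61 chaperones and 0.407 for 2227 others in the fit, but over the 6 fed pairs the mean gap of -0.111 was within its SD of 0.181 (up to 0.116), and of the 13 lists called in starved corals 3 had lower ratios than chaperones and 9 higher ones, from 0.107 (circadian clock) to 1.59 (digestive enzymes). Feeding, the hypothesis the design names, may account for the smaller rise (difference -0.322), but each condition was 1 aquarium, and feeding and aquarium cannot be told apart.

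Photosynthesis transcripts fell under high light in starved and in fed corals. A scan batch effect is argued against by list medians of -1.22 at the highest and -1.71 at the lowest over both batches and both comparisons. Less symbiont RNA in the high light extracts predicts that other symbiont transcripts fell alike, and the brighter 102 of the 204 probes named for the symbiont had medians of only -0.171 in starved and -0.148 in fed corals, which by the first bound set for this test would have put this explanation aside. It stays open because those probes split: 35 of the 102 (34.3%) fell by at least 50% of the photosynthesis median in starved corals, with a median of -1.67, while 29 lay within 0.3 of no change and 27 above 0.3 (14 in fed corals), which less symbiont RNA alone does not predict, so the name may take in probes of coral genes. Loss of symbionts or their RNA, lower transcript levels within symbionts and an aquarium effect cannot be told apart here.

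Feeding pairs 1 and 4 ran against feeding pairs 2, 5 and 6 across probes. Turned dye labels of pairs 1 and 4 could not be decided. Their mean correlation was 0.562 with the starved light pairs that share their starved extract. It was -0.261 with the fed light pairs that share their fed extract. Crossed pairs without a shared extract gave similar values, a mean of 0.503 with starved light pairs 4 and 1. Feeding pair 1 stood at -0.231 with fed light pair 4, and feeding pair 4 at -0.159 with fed light pair 2. These signs therefore need not come from the shared extracts. The fed extract was in Cy3 in pairs 1 and 4 and in Cy5 in pairs 2 and 5, so that among these the split follows dye orientation. Pair 6 was measured in both orientations. Dye bias is argued against by the mean correlation of -0.339 with the array of feeding pair 6 that has the same dye orientation as pairs 1 and 4. This rests on 1 array. Starved extracts 1 and 4 may share a state, since feeding pair 1 correlated with starved light pair 4, and feeding pair 4 with starved light pair 1, at a mean of 0.503 without a shared extract, against at most 0.186 with starved light pairs 2 and 3. Correlations with other extracts, each set against the mean of its condition, were mixed. With high light fed extract 4, starved extracts 1 and 4 stood at -0.552 and 0.404, and with high light starved extract 3 at 0.182 and 0.326. What that state is was not tested.

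Of 78 groups of pairs examined, 3 held a pair far from the others, where chance gives about 1 in 20. The innate immunity median was -0.169 in fed light pair 3, against -0.0979 to -0.0640 in the other 5 pairs. It was 0.110 in feeding pair 1, against -0.0040 to 0.0204 in the other 4 pairs. The nutrient transport median was -0.0171 in feeding pair 2, against 0.0239 to 0.0317 in the other 4 pairs.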

How the results depend on the processing

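The settings by scan batch, without the repeat arrays and without low light starved extracts 1 and 4, and the list tests with single pairs left out, were chosen after seeing the data. No called gene or list changed direction in the settings in which it was tested. Neither genes nor lists were tested in the batch and slide settings, or without the repeat arrays or low light starved extracts 1 and 4. Nor were they tested with array weights, other variance models, unaveraged arrays or a comparison's own arrays. The antioxidant median in fed corals was -0.0011 in the second scan batch alone. Over the settings, 136 of 199 counts of probes and 110 of 125 counts of lists lay within 1.5 times the reported ones. On their side of the threshold stayed 2375 of 2461 values of named genes and 1122 of 1247 of lists. The 84 gene calls that were lost had a median 0.988 of the reported change (range 0.124 to 2.42). In all 18 settings the correlation of the light responses moved by less than 0.118, the SD over the 24 combinations of single pairs. That SD is not a spread of the fitted correlation itself. Aquantile normalization moves no log ratio and tests nothing, and these tallies include it. In the order light in starved corals, light in fed corals, feeding in low light, difference of the light responses and feeding in high light, the reported counts are 4719, 2357, 1, 1096 and 435 probes. The counts that moved by over 1.5 times follow; beyond fewer arrays or another threshold, the cause was not tested. Without background correction, feeding gave 0. The scanner software's processed signals gave 0 for feeding (1 list) and 230 for feeding in high light. Median centring gave 2580, 765, 0, 47 and 8 (1 list for feeding), and the authors' deposited values gave 0, 699 and 202 for the last 3. Only probes well above background in all channel measurements gave 4 lists for feeding. For feeding alone, no dye term gave 0, the slide as a random block 3, the pair as a random block over 18 arrays 3, trended and robust variances 2 and the scan batch as a random block over 18 arrays 6. The older slide set alone gave 790, 0, 200 and 5 for the last 4, and the newer one 68, 442, 0, 1 and 1. Each comparison's own arrays gave 2893 for light in starved corals and 0 for feeding. Array weights gave 2, 2084 and 761 for the last 3, and separate channels 7, 1660 and 946. Replicate numbers pair the extracts only in part. Between same-numbered extracts of different arrays, 10 of 18 correlations were over 0.1 (median 0.118). Between differently numbered extracts of different arrays, 41 of 147 were (median -0.113). High light starved extract 2, for example, stood at 0.797 with high light fed extract 2. It stood at 0.706 with low light fed extract 1, but at -0.372 with low light fed extract 2. With the replicate number as a block, separate channels gave 6 for feeding and 907 for feeding in high light. At an adjusted p under 0.10, 2 probes were called for feeding. At least 1.5-fold, 1768, 581 and 626 probes were called for light in starved corals, in fed corals and their difference. With an estimated correlation 4, 6, 0, 2 and 2 lists were called, against 13, 12, 2, 10 and 10, and fry called 21 for light in starved corals and 0 for feeding. The first scan batch alone gave 831, 0, 239 and 7 for the last 4, and the second 654, 0, 469 and 44. Without low light starved extracts 1 and 4, the counts were 2884 for light in starved corals, 0 for feeding and 196 for feeding in high light. Leaving out single pairs gave 3569 to 4991, 1751 to 2577, 0 to 3, 615 to 1223 and 239 to 447, correlations of 0.681 to 0.739, and 13 to 15, 9 to 13, 0 to 4, 10 to 12 and 7 to 13 lists. Signal over background limits the dim probes: 5890 of 14394 were well above it in every channel measurement.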

Other observations

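Some enzymes of central metabolism fell under high light while others of the same pathway rose; the probes named here were chosen after their values were seen. In starved and fed corals, the phosphoglycerate kinase PGK stood at -1.84 and -1.61, G3PG, a glyceraldehyde-3-phosphate dehydrogenase, at -1.85 and -1.45, and the enolase ENOG at -1.44 and -1.23, all called, while another phosphoglycerate kinase, PGK1, rose by 0.70 and 0.40. In respiration, COX1_METSE and COX1_PLAFA stood at -2.13 and -2.09 in starved and at -1.67 and -1.59 in fed corals, and COX17, a copper chaperone of the same oxidase, rose by 0.87 and 0.44. Of the probes named PCNA, the sliding clamp of replication, PCNA_ORYSJ stood at -1.42 and -1.31 and PCNA_POPNI at -1.01 and -1.03, while PCNA_MACFA rose by 1.07 and 0.61. The names do not say whether a probe measured the coral or its symbiont, and this was not tested.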
